A study of Mus musculus with 6 samples.

How the data were processed

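RNA was sequenced from 4 libraries of E14 mouse embryonic stem cells treated with 10 µM paraquat for 15 h, 2 from wild-type and 2 from Pml knockout cells, and the labels give each library's genotype and replicate number. The other 2 of the 6 samples, proximity-labelled PML chromatin, were not analysed here. The labels describe polyadenylated RNA. Their library kit entries name the same RNA kit for wild-type replicate 1 and for both knockout replicates; the entry of knockout replicate 2 also names a DNA kit, for the chromatin samples. The entry of wild-type replicate 2 names that DNA kit alone. Whether this library was prepared differently is not given in the sources used here.

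Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with TopHat and tested with edgeR, on the mm10 genome; versions, the annotation, the treatment of reads matching several genes and the use of strand are not given in the sources used here. The deposited table holds 24421 genes by symbol, with a CPM value per library (reads per 1000000) and the authors' log2 fold change, mean log2 CPM, p-value and false discovery rate. The authors' log2 fold change was wild type over knockout: its sign equalled that of wild type minus knockout in all 824 of their called genes with a mean of at least 1 CPM.

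The deposited CPM values sum to 1000000 per library, and low values are whole multiples of the value of 1 read. Dividing by that step gave whole reads for 100% of values within a tolerance of 0.001 reads, and totals of 31384794 and 44130093 reads in wild type and 38150397 and 43715807 in the knockout. The 10 most abundant genes took 4.13 to 4.38% of reads. No read was found for 5660 genes. With these depths 1 CPM is about 31 to 44 reads, so counting error adds to the spread of the lowest tested genes, some of which have far fewer reads in 1 group; the number of libraries limits precision for the others.

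The design fixed before the data were examined named a count test for counts and limma for normalized values; since the deposited unit is CPM, limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1) was used, over the 12710 genes with a mean of at least 1 CPM, with genotype as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. A count test on the recovered reads (edgeR 4.0.16, quasi-likelihood with TMM and filterByExpr), added after seeing the data, called 620 of 14782 genes, 596 of them shared with the limma calls. Gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 on the same log2(CPM + 1) values, in place of the log2 CPM with prior count planned for counts, with at least 5 tested genes per list and adjustment over 24 lists. 12 lists passed. Of these, 0 passed with an estimated correlation. With fry, which asks whether a list's genes move one way, 1 passed, the 2-cell-like state genes (adjusted p = 0.0457). With 4 libraries the test with an estimated correlation has few degrees of freedom, so its failures do not show that correlated genes made the calls. They do not exclude it either. Estimates for called lists ranged up to 0.296 for neuroectoderm genes, with 0.286 for ERK targets and 0.166 for glycolysis and hypoxia response genes. For such lists the preset value may make p too small. Some called lists lay below it, such as NRF2 targets at 0.00104. The 2-cell-like state list had an estimated correlation of -0.0473, below the preset value. Its unadjusted camera p still rose from 3.68e-10 to 0.022. Of the list of mitochondrially encoded genes, 0 were in the table, so it has no result. Chromosomes and mm10 coordinates came from a RefSeq gene table of GRCm38.p6: 23204 symbols matched directly, 1096 by a unique older symbol, and 121 not.

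Named genes followed a rule set in advance: Pml; the 12 genes with the largest called change in each direction whose libraries did not overlap and whose symbol is not a predicted or clone name; up to 4 called members of each list by smallest adjusted p; all tested Y-linked genes; and every member of a list with 5 or fewer tested genes. Genes named outside this rule are said to be chosen after their values were seen, except X-linked copies and low-count Y genes given for comparison with the Y-linked genes. Intervals on residual Y-gene levels are exact binomial (Clopper-Pearson) on reads summed per group.

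The test was tried on simulated counts for this comparison with known changes in 200 genes, over 12680 tested genes. The cell cycle list was also shifted by a known amount, and its genes are not among the 200. It called 58% of 1.25-fold, 88% of 1.5-fold, 95.9% of 2-fold and 100% of 4-fold changes with the right sign. Of its calls 6.25% had no simulated change, and 0 of 23 unchanged lists were called. Genes were simulated independently, so the last count does not cover lists whose genes vary together. Estimated correlations in the data were 0.296 for neuroectoderm genes and 0.286 for ERK targets. Replicates were not duplicates: chi-square per degree of freedom was 6.16 between wild-type and 8.14 between knockout libraries. Pearson r of log2 values across genes, which are not independent replicates, was 0.997 within groups and 0.993 to 0.995 between them. Alternatives were other scalings (DESeq2 size factors by edgeR's RLE, upper quartile, TMM), no filter or a minimum mean count, a pseudocount of 0.1, a replicate block, leaving out each library, a minimum fold of 1.5 (treat), count tests (edgeR exact, edgeR quasi-likelihood, DESeq2 1.42.0) and leaving out chromosome 8 or 8 and Y. With a library left out, the lone library of its group was assumed to vary like the others.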

Results

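Gene expression was measured by RNA sequencing in E14 mouse embryonic stem cells, a widely used male line, after 15 h in 10 µM paraquat, a redox cycler that generates superoxide in cells. Wild-type cells (n = 2 libraries) were compared with cells homozygous for a disrupted Pml gene (n = 2 libraries). Pml encodes the scaffold protein of PML nuclear bodies. All 4 libraries came from treated cells, so the comparison addresses how cells with and without Pml differ under this treatment, and it does not measure the response to paraquat. The medium contained leukemia inhibitory factor, the GSK3 inhibitor CHIR99021 and the MEK inhibitor PD0325901. The same series holds 2 samples of PML body-associated chromatin labelled by a peroxidase fused to PML, which were not analysed here. Library depth was 31384794 and 44130093 reads in wild type and 38150397 and 43715807 reads in the knockout. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each value below is a mean of library-size-scaled read counts (CPM, reads per 1000000 reads counted in genes) ± SD with n = 2, and each log2 fold change (knockout minus wild type) is on the log2(CPM + 1) scale, which understates the change of low genes.

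The Pml transcript fell in the knockout, and part of it remained. Its level was 233 ± 7.495 CPM in wild type (238 and 228 in the 2 libraries) and 84.2 ± 7.80 CPM in the knockout (78.7 and 89.7), so that 36.2% of the wild-type level was left. The log2 fold change was -1.46 with a standard error of 0.059 (limma, adjusted p = 4.43e-10). Pml lies on chromosome 9 from 58217179 to 58249796 (mm10). The table counts reads over the whole gene, and which part of it was disrupted is not given in the sources used here, so the level of intact transcript was not measured.

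Across the transcriptome, many genes differed by small amounts. Of 12710 genes tested with limma, 687 passed an adjusted p of 0.05, of which 248 were higher and 439 lower in the knockout. Their median absolute log2 fold change was 0.36, and 529 of them differed by less than 1.5-fold. At least 2-fold differences on this scale were found in 33 genes, and 32 of these were lower in the knockout. The exception was Gm5089, a predicted gene named here after its values were seen, at 0.18 ± 0.07 CPM in wild type and 2.79 ± 0.46 CPM in the knockout (log2 fold change 1.68, SE 0.18, limma adjusted p = 4.35e-05). In plain CPM other low genes called higher also rose more than 2-fold, such as Plac8 (2.88-fold) and Zscan4c (2.46-fold). The count was 439 without wild-type library 1, 869 without wild-type library 2, 669 without knockout library 1 and 367 without knockout library 2; it was 298 with no filter on low values and 1198 with the replicate number as a block. The authors' deposited table, from edgeR over 24421 genes, held 927 genes at a false discovery rate under 0.05. Of these, 580 were higher in wild type and 347 higher in the knockout. Limma called 646 of the 927 here, 178 were tested and not called, and 103 had a mean under 1 CPM.

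**Figure D1:**
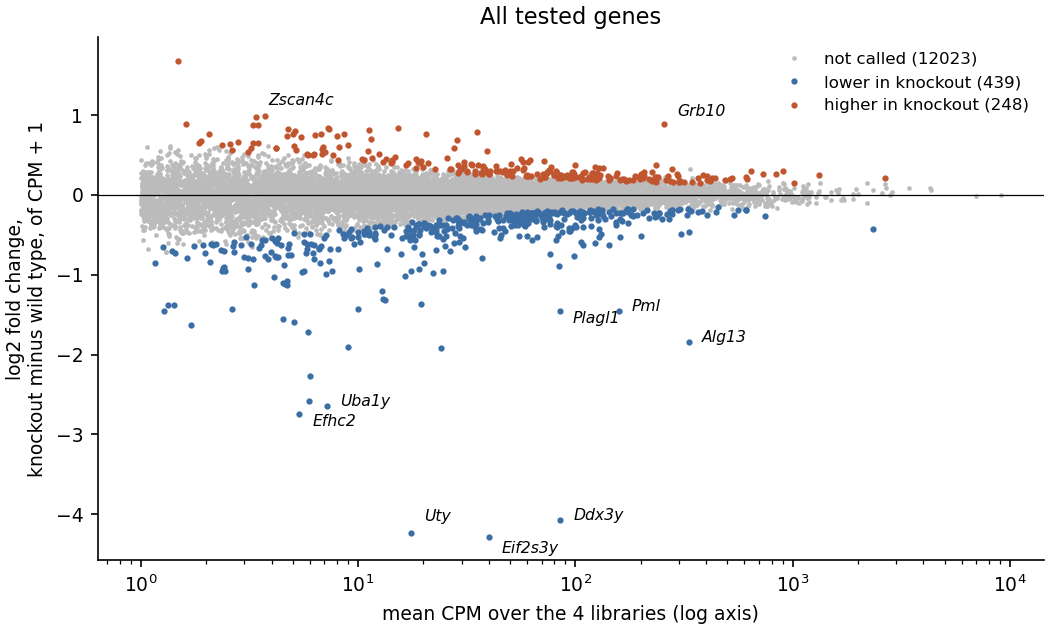
Each point is one of the 12710 tested genes, with its mean CPM over the 4 libraries on a log axis and its log2 fold change (knockout minus wild type, of CPM + 1) on the vertical axis; blue and orange mark the 439 lower and 248 higher genes at a limma adjusted p under 0.05. The Y-linked genes Ddx3y, Eif2s3y and Uty lie lowest, near -4, and most called genes lie close to 0.

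The 3 largest decreases on the log2 scale were in genes of the Y chromosome. Ddx3y, an RNA helicase gene, fell from 162 ± 2.40 to 8.72 ± 0.27 CPM, an 18.6-fold difference (log2 fold change -4.07, SE 0.068, limma adjusted p = 4.28e-15). Eif2s3y, which encodes a translation initiation factor subunit, fell from 76.9 ± 2.30 to 3.03 ± 0.46 CPM, and Uty, a histone demethylase paralog, from 34.1 ± 2.78 to 0.87 ± 0.23 CPM. Uba1y, a ubiquitin-activating enzyme gene, fell from 13.2 CPM in both wild-type libraries to 1.26 ± 0.10 CPM. All 4 Y-linked genes tested were lower, and they lie between positions 818612 and 1286628 of chromosome Y (mm10). In the knockout 2.61% of the wild-type level remained for Uty (exact 95% interval from the reads 2.03 to 3.29%), 3.92% for Eif2s3y (3.44 to 4.46%), 5.36% for Ddx3y (4.96 to 5.78%) and 9.54% for Uba1y (7.71 to 11.7%). These intervals cover counting error only. Zfy1 and Kdm5d were below the filter, with 93 and 40 reads in the wild-type libraries against 6 and 2 in the knockout libraries, and Usp9y had 22 reads against 12. Each of the tested genes has a similar X-linked copy, and the sources used here do not say how reads matching both were counted. The X-linked copies Eif2s3x and Kdm6a stood at 143 ± 0.76 and 105 ± 1.90 CPM in wild type and 144 ± 4.39 and 105 ± 1.43 CPM in the knockout. Uba1 was at 645 ± 14.4 CPM in wild type and 683 ± 16.3 CPM in the knockout (adjusted p = 0.318). Ddx3x was at 960 ± 12.2 CPM in wild type and 1067 ± 0.39 CPM in the knockout (log2 fold change 0.15, adjusted p = 0.0433), a call that ended without either wild-type library (highest adjusted p = 0.309) and under TMM scaling (adjusted p = 0.052).

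**Figure D2:**
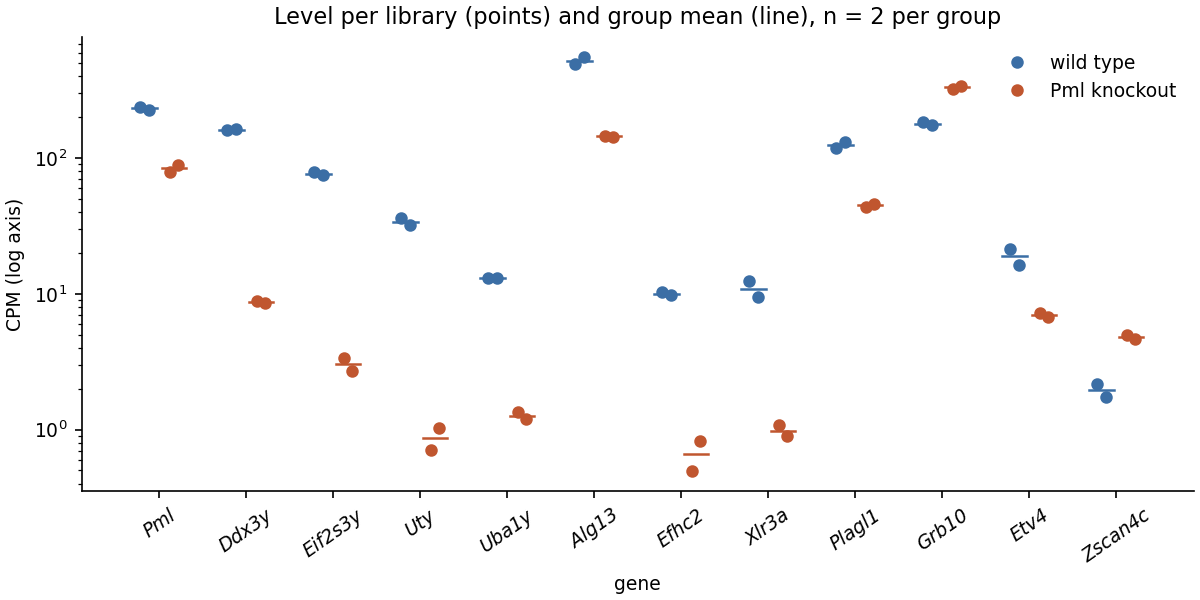
Level of 12 named genes in CPM on a log axis; points are the 2 wild-type (blue) and 2 Pml knockout (orange) libraries and short lines are group means. For every gene drawn the libraries of the 2 groups do not overlap, with Uty at 34.1 against 0.87 CPM and Grb10 at 180 against 333 CPM. The same holds for all 687 called genes and for 49.3% of tested genes, against 33.3% expected by chance.

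Besides the 4 Y-linked genes, the 12 largest decreases among genes chosen by the rule for named genes included 5 of the X chromosome. Alg13, which encodes a subunit of the enzyme for the second sugar of N-glycans, fell from 523 ± 42.1 to 145 ± 0.96 CPM (3.62-fold, log2 fold change -1.85, SE 0.052, limma adjusted p = 3.51e-12). Efhc2, an EF-hand protein gene, fell 15.2-fold, from 10.0 ± 0.32 to 0.66 ± 0.23 CPM. Xlr3a and Xlr3c, members of a multi-copy lymphoid-regulated family, fell 11.1-fold and 7.57-fold from 10.9 ± 2.14 and 10.6 ± 1.08 CPM, and Pnma5, a paraneoplastic antigen family gene, fell 4.08-fold from 38.7 ± 3.51 CPM. The Xlr copies share sequence, so the level of each copy is uncertain. The other 3 of these 12 were AI662270 on chromosome 11 (4.63-fold), Ushbp1 on chromosome 8 (4.31-fold) and the imprinted noncoding Peg13 on chromosome 15 (9.56-fold, from 3.10 ± 0.22 to 0.32 ± 0.13 CPM). AI662270 has a clone-type symbol that the name patterns of the rule did not cover.

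Imprinted genes, which are expressed from one parental allele, mostly fell in the knockout. Of 25 tested, 15 fell and 3 rose, and adjusted over the list alone 16 fell and 3 rose; the list median was -0.47 (camera, adjusted p = 4.42e-09, and adjusted p = 0.401 with an estimated correlation). Plagl1, a zinc finger growth regulator, fell 2.77-fold, from 124 ± 8.999 to 44.9 ± 2.00 CPM (log2 fold change -1.45, SE 0.063, limma adjusted p = 8.98e-10). Impact fell from 386 ± 6.51 to 279 ± 6.70 CPM and the noncoding Rian from 152 ± 10.2 to 105 ± 0.83 CPM. Grb10, an adaptor that restrains growth factor signalling, rose from 180 ± 6.91 to 333 ± 11.9 CPM (1.85-fold, log2 fold change 0.88, SE 0.047, adjusted p = 1.49e-08). Peg13 lies within another gene and whether counting used strand is not given in the sources used here, so its level is uncertain.

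Genes of the 2-cell-like state, a transient state of a small part of embryonic stem cells that resembles the early embryo, rose in the knockout. Of 13 tested, 9 rose and 1 fell, and adjusted over the list alone 12 rose and 1 fell; the median was 0.65 (camera, adjusted p = 4.42e-09, and adjusted p = 0.401 with an estimated correlation). Zscan4c rose 2.46-fold from 1.96 ± 0.30 to 4.80 ± 0.25 CPM, and Zscan4a from 5.04 ± 0.72 to 9.66 ± 0.76 CPM. Usp17le and Usp17lc, deubiquitinase genes of a multi-copy family, rose 2.19-fold and 2.24-fold, and Usp17lb of the same family, which is not on the list, rose 2.25-fold. Gm8300 rose 1.84-fold. The calls of Usp17le, Usp17lc and Gm8300 ended without knockout library 2 (highest adjusted p = 0.156, for Usp17lc). Copies of the Zscan4 and Usp17l families share reads, so single members are uncertain. The member that fell was Pramel7, at 6.86 ± 0.20 CPM in wild type and 2.58 ± 0.09 CPM in the knockout, which acts in naive pluripotency.

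Targets of ERK signalling fell, in cells grown with the MEK inhibitor PD0325901. ERK activity itself was not measured. Of 15 tested, 7 fell and none rose, and adjusted over the list alone 10 fell; the median was -0.30 (camera, adjusted p = 3.06e-07, and adjusted p = 0.411 with an estimated correlation). Etv4, an ETS transcription factor, fell from 18.97 ± 3.59 to 7.001 ± 0.29 CPM (2.71-fold, log2 fold change -1.31, SE 0.12, limma adjusted p = 1.15e-05). The feedback inhibitors Spry4 and Dusp6 fell from 6.77 ± 3.00 to 2.49 ± 0.71 CPM and from 17.0 ± 3.29 to 10.1 ± 0.30 CPM. These genes also differed between wild-type libraries 1 and 2, at 8.89 and 4.65 CPM for Spry4. The levels there were 21.5 and 16.4 CPM for Etv4 and 19.3 and 14.7 CPM for Dusp6. Spred2 fell from 62.6 ± 1.97 to 50.7 ± 4.07 CPM, a call that ended without wild-type library 1 or knockout library 1 (highest adjusted p = 0.0917). Among WNT targets, with the GSK3 inhibitor CHIR99021 in the medium, 0 of 9 tested passed (camera, adjusted p = 0.115, and fry, adjusted p = 0.173).

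**Figure D3:**
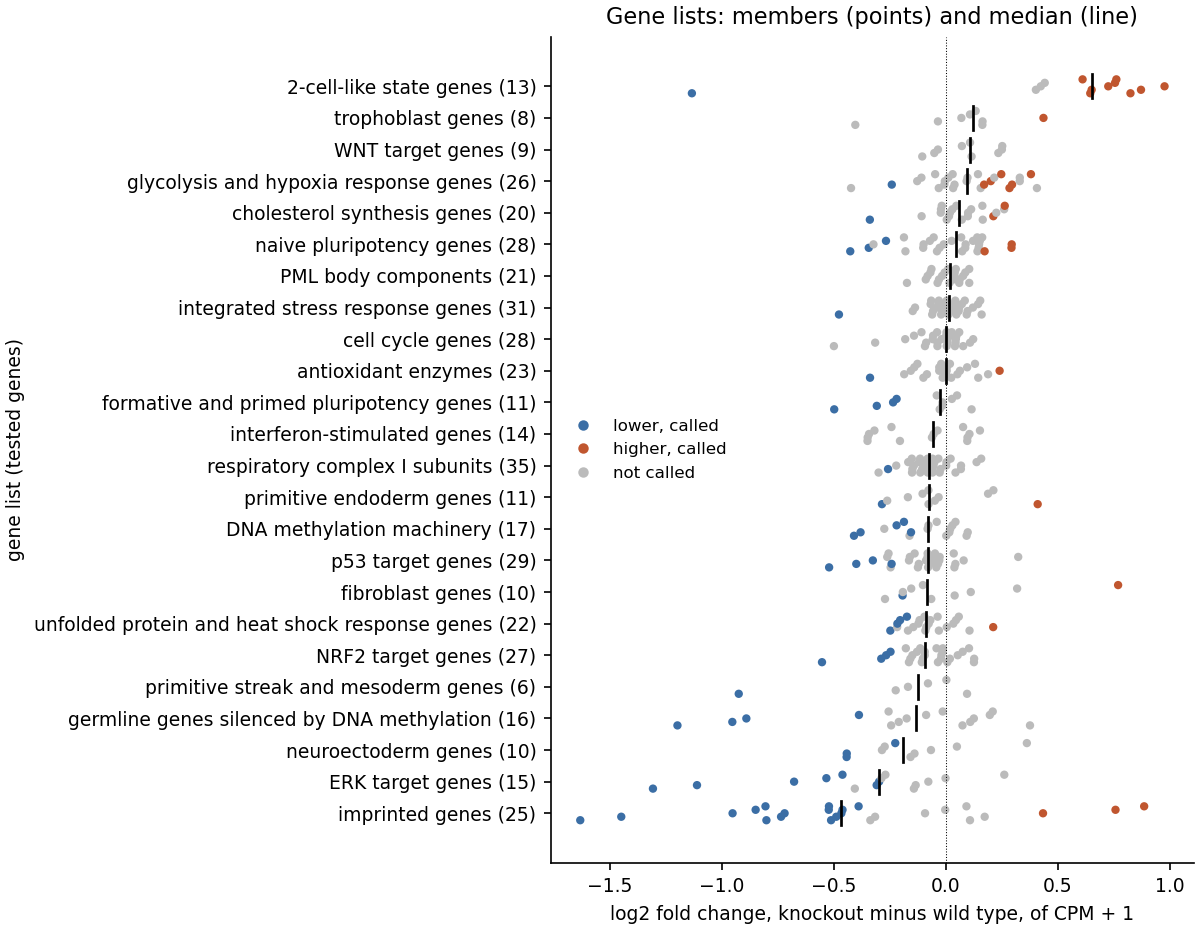
Log2 fold change (knockout minus wild type, of CPM + 1) of the tested members of each gene list with at least 5 tested genes; points are genes, coloured by their call over all 12710 genes, and the black line is the list median. Medians run from -0.47 for imprinted genes to 0.65 for 2-cell-like state genes.

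Genes of oxidative and other stress responses changed little. Among NRF2 targets, which detoxify electrophiles and reactive oxygen, 4 of 27 fell and none rose (6 adjusted over the list alone), with a median of -0.09 (camera, adjusted p = 0.0103, and adjusted p = 0.401 with an estimated correlation). Ephx1 fell from 29.6 ± 0.84 to 19.9 ± 2.27 CPM and Gsr, glutathione reductase, from 146 ± 3.19 to 121 ± 6.16 CPM. Nqo1 fell 1.23-fold and Me1 1.19-fold, calls that ended without wild-type library 1 or knockout library 1 (for Me1, without each of the 4 in turn; highest adjusted p = 0.177 for Nqo1 and 0.108 for Me1). Gsr and Nqo1 lie on chromosome 8, whose genes were lower as a whole (below); the list's call ended without the genes of that chromosome (adjusted p = 0.0647) and without wild-type library 2 (adjusted p = 0.0952). Of 23 tested antioxidant enzymes Prdx6 rose 1.18-fold and Gpx3 fell 1.27-fold, calls that ended without wild-type library 1 (adjusted p = 0.0618) and knockout library 2 (adjusted p = 0.0585) respectively; the list gave a camera adjusted p of 0.755, with a mean and median below 0 and a test direction above it. Of 31 integrated stress response genes Cebpb fell 1.41-fold, and the list did not pass (camera, adjusted p = 0.5). Camera looks for a shared direction. The mixed test of fry, which asks whether a list's genes change in either direction, gave adjusted p = 0.00757 for antioxidant enzymes. For integrated stress response genes it gave 0.0122. This test asks for any change, not for more change than in other genes, and most lists passed it. Of all 12710 tested genes, 2454 had an unadjusted limma p under 0.05. The mixed results are therefore not particular to these lists. Among genes of the unfolded protein and heat shock responses 4 of 22 fell and 1 rose (7 and 1 adjusted over the list alone; camera, adjusted p = 0.00295, adjusted p = 0.401 with an estimated correlation, and adjusted p = 0.0725 without wild-type library 2). The chaperone Hspb1 fell from 581 ± 8.56 to 489 ± 1.46 CPM, Pdia4 fell 1.153-fold and Edem1 1.16-fold, and Hsp90aa1 rose 1.16-fold. The call of Edem1 ended without each of 3 libraries in turn (wild-type 1 and 2 and knockout 2, highest adjusted p = 0.206) and that of Hsp90aa1 without wild-type library 1 (adjusted p = 0.145).

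Among p53 targets 4 of 29 fell and none rose (4 fell and 1 rose adjusted over the list alone), with a median of -0.08 (camera, adjusted p = 0.000487, and adjusted p = 0.401 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, fell from 182 ± 17.5 to 145 ± 1.46 CPM, Epha2 from 190 ± 16.6 to 132 ± 4.96 CPM, and Btg2 1.33-fold. Plk2 fell 1.19-fold, a call that ended without wild-type library 2 or knockout library 2 (highest adjusted p = 0.126). Other components of PML bodies, among them Daxx and Atrx, gave 0 of 21 tested genes past the threshold (camera, adjusted p = 0.68; fry, adjusted p = 0.689). Interferon-stimulated genes gave 0 of 14 (camera, adjusted p = 0.293, and fry, adjusted p = 0.563). Cell cycle genes gave 0 of 28 (camera, adjusted p = 0.507, with a median above and a mean below 0, and fry, adjusted p = 0.363). The mixed test of fry, for changes in either direction, which most lists passed, gave adjusted p = 0.0377 for cell cycle genes. It gave 0.343 for PML body components and 0.484 for interferon-stimulated genes. Of 3 tested replication-dependent histone genes, Hist3h2a, Hist1h2bc and Hist1h1c, none passed (log2 fold changes -0.06, 0.03 and -0.03).

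Glycolysis and hypoxia response genes rose by small amounts, with 6 of 26 higher and 1 lower (11 and 2 adjusted over the list alone) and a median of 0.09 (camera, adjusted p = 0.000907, and adjusted p = 0.411 with an estimated correlation). The glucose transporter gene Slc2a3 rose from 1212 ± 46.8 to 1438 ± 2.03 CPM, triosephosphate isomerase Tpi1 from 203 ± 9.33 to 247 ± 12.9 CPM, and lactate dehydrogenase Ldha 1.148-fold, a call that ended without wild-type library 1 (adjusted p = 0.257). Phosphofructokinase Pfkp fell 1.18-fold. Subunits of respiratory complex I had a median of -0.08 (camera, adjusted p = 0.0119, and adjusted p = 0.411 with an estimated correlation), and 1 of 35 passed over all genes, Ndufb6 (1.199-fold lower), with 0 adjusted over the list alone; the list's call ended without 3 of the 4 libraries (highest adjusted p = 0.0982, without wild-type library 1), and that of Ndufb6 without wild-type library 1 or knockout library 2 (highest adjusted p = 0.239). Cholesterol synthesis genes gave 2 higher and 1 lower of 20 (3 and 1 adjusted over the list alone; camera, adjusted p = 0.0364, adjusted p = 0.411 with an estimated correlation, and adjusted p = 0.304 without wild-type library 1, 0.197 without knockout library 2, 0.0679 with no filter and 0.11 without chromosome 8 genes). Sqle rose 1.16-fold and Dhcr7 1.21-fold (calls that ended without wild-type library 1 or knockout library 2, highest adjusted p = 0.119 and 0.305), and Insig1 fell 1.27-fold.

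Genes of the DNA methylation machinery fell slightly, 5 of 17 with none higher (6 adjusted over the list alone), at a median of -0.08 (camera, adjusted p = 0.016, adjusted p = 0.411 with an estimated correlation, and adjusted p = 0.157 without wild-type library 1 and 0.0765 without knockout library 2). Dnmt3l, a cofactor of the de novo methyltransferases, stood at 175 ± 28.6 CPM in wild type and 133 ± 3.73 CPM in the knockout, and Tet3, Uhrf1 and Dnmt3a fell 1.35-fold, 1.14-fold and 1.17-fold. Each of these 4 calls ended without 2 of the libraries in turn: Dnmt3l (highest adjusted p = 0.0667) and Dnmt3a (0.251) without wild-type library 1 or knockout library 2, Tet3 (0.0577) without wild-type library 1 or knockout library 1, and Uhrf1 (0.0741) without either wild-type library. Germline genes that DNA methylation silences in other cells fell as well, 4 of 16 with none higher (5 adjusted over the list alone), at a median of -0.13 (camera, adjusted p = 0.016, and adjusted p = 0.411 with an estimated correlation). The meiotic gene Hormad1 fell 2.47-fold, from 18.4 ± 1.96 to 7.47 ± 0.92 CPM, and the testis tubulin Tuba3a 1.87-fold, from 110 ± 4.36 to 58.9 ± 2.35 CPM. Its near-identical copy Tuba3b fell 2.62-fold, with reads that the 2 genes may share. Dazl fell 1.33-fold, a call that ended without wild-type library 1 or knockout library 1 (highest adjusted p = 0.107).

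Markers of pluripotency went in both directions. Of 28 naive pluripotency genes 3 rose and 3 fell (9 and 6 adjusted over the list alone; camera, adjusted p = 0.343, with a median above and a mean below 0). Zfp42, also known as Rex1 and located on chromosome 8, fell from 812 ± 21.6 to 674 ± 30.0 CPM and Klf5 from 172 ± 11.99 to 135 ± 12.2 CPM. Nr5a2 rose 1.23-fold and Tfcp2l1 1.22-fold, calls that ended without knockout library 2 (adjusted p = 0.0594 for Nr5a2) and, for Tfcp2l1, also without wild-type library 1 or knockout library 1 (highest adjusted p = 0.319). Of 11 formative and primed genes 4 fell and none rose, also adjusted over the list alone (camera, adjusted p = 0.0501; it passed with no filter, 0.013, without knockout library 2, 0.0212, without chromosome 8 genes, 0.0461, with the replicate block, 0.0472, and with DESeq2 size factors, 0.048, and gave 0.0506 to 0.411 under the others). These were Foxd3 (1.247-fold), Pou3f1 (1.49-fold), Zic2 (1.18-fold) and Dnmt3a; the calls of the first 3 each ended without either knockout library and without 1 wild-type library (library 1 for Foxd3 and Zic2, library 2 for Pou3f1; highest adjusted p = 0.226, 0.183 and 0.326 for Foxd3, Pou3f1 and Zic2).

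Of the lists for cell types that a culture could also hold, neuroectoderm genes fell, 3 of 10 with none higher (3 lower and 1 higher adjusted over the list alone), at a median of -0.19 (camera, adjusted p = 0.00493, adjusted p = 0.411 with an estimated correlation, and adjusted p = 0.0759 without knockout library 1). Nes fell from 43.2 ± 1.98 to 31.5 ± 1.2 CPM, Sox1, on chromosome 8, from 19.9 ± 0.93 to 14.3 ± 0.35 CPM and Stmn2 1.17-fold. By camera, lists of primitive endoderm (1 higher and 1 lower of 11, camera adjusted p = 0.526), primitive streak and mesoderm (1 lower of 6, adjusted p = 0.223), trophoblast (1 higher of 8, adjusted p = 0.206) and fibroblast genes (1 higher and 1 lower of 10, adjusted p = 0.755) did not pass. The mixed test of fry, for changes in either direction, which most lists passed, gave adjusted p = 0.294, 0.039, 0.0116 and 0.0724 for these lists in the same order. Their changed members were Lamb1 (1.33-fold higher), Col4a1 (on chromosome 8, 1.22-fold lower, a call that ended without knockout library 2, adjusted p = 0.121), Bmp4 (2.04-fold lower, from 13.5 ± 2.18 CPM), Tfap2c (1.36-fold higher), Tagln (1.90-fold higher) and Vim (1.14-fold lower, a call that ended without wild-type library 1, wild-type library 2 or knockout library 1, highest adjusted p = 0.0859). Adjusted over the list alone the counts higher and lower were 1 and 1 for primitive endoderm, 0 and 1 for streak and mesoderm, 1 and 1 for trophoblast and 1 and 1 for fibroblast genes, whose median and mean differed in sign. Among the other genes with the largest increases, Grb10 and Accsl were well expressed, the second rising 1.76-fold from 25.7 ± 2.68 CPM; Lrrc15 rose 1.74-fold from 15.0 ± 1.41 CPM, and Plac8, Mobp and Aldh3a1 rose 2.88-fold, 1.95-fold and 2.02-fold from levels under 5 CPM.

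Genes of chromosome 8 were lower in the knockout as a set. The median log2 fold change of its 681 tested genes was -0.06, 70.6% of them were below 0, and 52 were called lower against 8 higher. The medians of the other autosomes lay between -0.02 and 0.02 with 43.5 to 56.2% of genes below 0, and that of chromosome X was 0.03. Relative to the mean of the 4 libraries, the chromosome 8 median was 0.049 and 0.020 in the wild-type libraries and -0.023 and -0.039 in the knockout libraries. On chromosome 8, 86.7% of calls were lower in the knockout, against 61.9% on the other autosomes. No p-value is given, since genes are not independent replicates. Without the genes of chromosomes 8 and Y, limma called 618 genes, 238 higher and 380 lower.

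**Figure D4:**
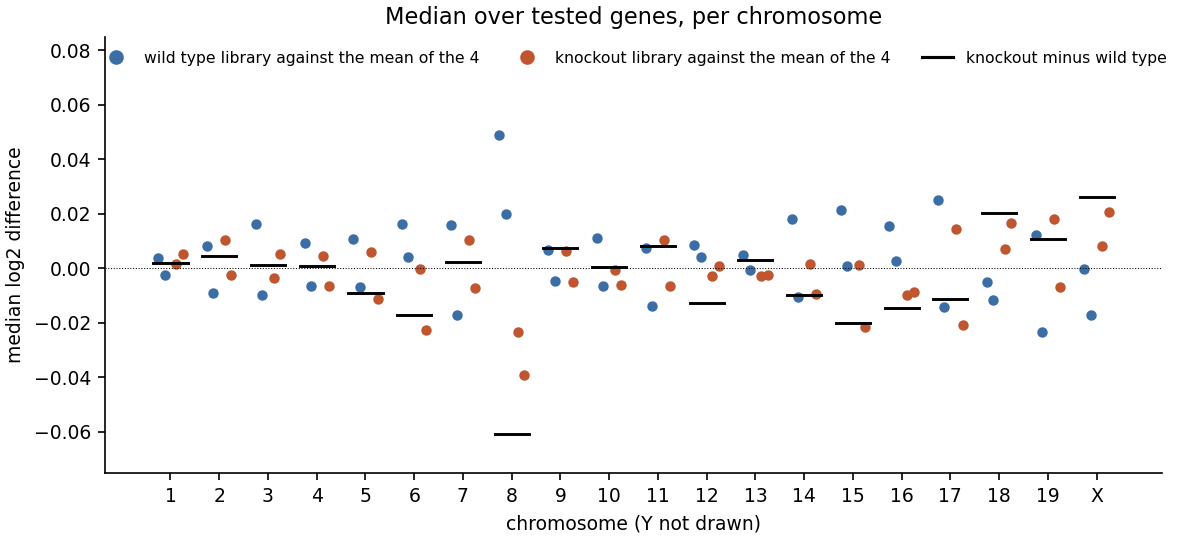
Median over tested genes of each chromosome on the log2 scale; points give each library's difference from the mean of the 4 libraries (blue wild type, orange knockout) and black lines the knockout minus wild type fold change. Chromosome 8 stands at -0.06, and the other autosomes between -0.02 and 0.02.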

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

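Chosen after seeing the data were TMM scaling, the edgeR quasi-likelihood test, the settings without chromosomes 8 or Y, and the chromosome medians with no filter or a pseudocount of 0.1. No called gene named in the report changed sign, and no call shared with limma had the opposite sign, under any setting. Against 687 calls (248 higher, 439 lower), no filter gave 298 (79 and 219, of which 271 were shared, over 18761 genes tested). A minimum fold of 1.5, which asks for a larger change, gave 24 (2 and 22) and ended the calls of 62 named genes. The edgeR exact test gave 387 higher, and the replicate block gave 1198 (478 and 720), among them all 687. The 2 pairs of same-numbered libraries deviated with a correlation of 0.12 and the labels name no culture, batch or day shared by number, so the number is not taken to pair them. An effect shared by number stays open, since that correlation was positive and calls rose with the block. Leaving out each library gave 367 to 869 calls, 107 to 311 higher and 260 to 558 lower; fewer samples enter these fits. Of 80 named called genes 53 kept their call without each library in turn; 30 lost it with no filter, 9 with DESeq2 and 3 with edgeR's quasi-likelihood test. Of 12 lists 6 lost their call without at least 1 library, and 0 passed with an estimated correlation and 1 with fry. The test with an estimated correlation has little power with so few libraries. The chromosome 8 median log2 fold change was -0.083 to -0.047 without each library and -0.040 with no filter. The chromosome Y median log2 fold change was -4.18 to -4.10 without each library, -1.86 with no filter, which adds genes near 0 CPM, and -4.415 with the smaller pseudocount. Where no construction is named, the cause was not tested. Fewer samples do not account for the rise in calls without wild-type library 2, whose cause was not tested either. Depth limits genes under about 1 CPM.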

Other observations

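The tests of explanations, the groupings of genes and the genes named here that the report does not name were chosen after the values were seen; the limma test and the leaving out of libraries were planned. All 5 tested Xlr genes fell (Xlr3a, Xlr3b, Xlr3c, Xlr4a and Xlr4b), with a median log2 fold change of -1.45. They lie beside Pnma5 on chromosome X, in an interval from the start of Pnma5 at 73033981 to the end of Xlr3c at 73265576 (mm10) that was set by these genes themselves, and F8a inside it was not called. Of 22 tested genes within 1 Mb on either side, 1, Magea4, fell and 0 rose. On the same chromosome Rhox5 fell from 8.07 ± 0.28 to 2.07 ± 0.79 CPM, Magea4 from 2.5045 ± 0.21 to 0.35 ± 0.10 CPM and Nxf3 from 6.71 ± 0.78 to 2.66 ± 0.17 CPM (n = 2 per group; limma log2 fold changes -1.59, -1.38 and -1.07). Of 20 tested meiosis genes 7 fell and none rose. Rec114, which acts in meiotic double-strand break formation, fell from 22.2 ± 0.05 to 10.5 ± 1.45 CPM, and the meiotic cohesin Smc1b from 29.6 ± 1.07 to 14.5 ± 0.25 CPM. Hormad1, Stag3 and Hormad2 fell too, while the calls of Tex11 and Tex15 ended when libraries were left out in turn (3 and 4 of the 4, highest adjusted p = 0.281 and 0.1).

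Of 11 tested Hedgehog pathway genes 3 rose and none fell. Gli1, a transcription factor that is itself a target of the pathway, rose from 21.6 ± 2.47 to 35.5 ± 1.98 CPM (n = 2 per group; limma log2 fold change 0.69, adjusted p = 0.00024), and its target Ptch1 from 61.2 ± 4.45 to 82.0 ± 0.35 CPM. Gli2 rose too, a call that ended without wild-type library 1 or knockout library 2 (highest adjusted p = 0.23). Fgfr2 rose from 8.50 ± 0.14 to 14.4 ± 0.37 CPM. Id3, a target of BMP signalling, fell from 9.76 ± 2.42 to 5.00 ± 0.25 CPM.

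The 5 Y-linked genes of at least 1 CPM in wild type fell to under 10% of it. Reads assigned instead to the X-linked copies are argued against for Eif2s3y and Uty, since Eif2s3x and Kdm6a gained 1.23% and 0.030% of the CPM that the Y genes lost (SE 4.27 and 5.06 percentage points). Ddx3x gained 69.2% of the CPM that Ddx3y lost (SE 5.63), so reads moved between these copies may contribute there; a real increase of Ddx3x would give the same values. Uba1 gained 313% of the loss of Uba1y (SE 129), too uncertain to decide. Loss of the Y chromosome from most knockout cells and silencing of its genes cannot be told apart. Loss would leave the same share of each gene, but the highest share kept was 3.66 times the lowest, and the intervals of Uty, Ddx3y and Uba1y do not overlap (2.03 to 3.29%, 4.96 to 5.78% and 7.71 to 11.7%); reads of X-linked copies counted to some Y genes would also give unequal shares, and silencing was not tested. Usp9y kept 50.3% on 12 reads (exact 95% interval 22.7 to 106%), too few to decide.

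Chromosome 8 was lower in the knockout along its length, with a median below 0 in 7 of its 7 segments of 20 Mb (-0.032 to -0.091). Scaling of the libraries is argued against by the other autosomes, whose largest absolute median was 0.020. A few strongly changed genes could hardly move a median over 681 genes, of which 70.6% were below 0. The median of -0.052 over genes not called therefore adds little as a test of them. A difference in chromosome 8 copy number in part of the cells is consistent with the 7 segments: over the 521 genes with a mean of at least 10 CPM the median was -0.067, or 4.54% lower, which 1 extra copy in 9.52% of wild-type cells would give. Which population differs from the normal number was not tested, and an effect of Pml on this chromosome stays open.

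The summed CPM of the Zscan4 copies was 14.2 and 12.1 in the wild-type libraries and 24.9 and 25.3 in the knockout libraries, and that of the Usp17l copies 8.60 and 7.91 against 17.8 and 17.5. Reads moved between copies are therefore argued against, the smaller log2 ratio of the 2 sums being 0.936. A larger share of cells in a 2-cell-like state would raise Zfp352 and Tmem92, outside both families. Their log2 ratios of 1.12 and 0.577 averaged 0.8485. Zfp352 rests on 39 and 96 reads per group, and Tmem92 was tested and not called. Both genes are on the 2-cell-like list, and Tmem92 is among its tested members. This check is therefore not independent of the rise that prompted it. Higher transcription per cell was not tested.

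A hypothesis that imprinted genes moved according to the parental allele they are expressed from was tested over the list. It did not hold for every called gene, and over the list as a whole the test could not decide it. The expressed allele was not measured in these cells. Of 16 paternally expressed genes on the list 10 fell and 0 rose, but of 8 maternally expressed genes 5 fell, against the direction of the hypothesis, and 3 rose (Grb10, Phlda2 and Cdkn1c). Dio3, also paternally expressed but not on the list, rose from 3.99 ± 0.41 to 6.36 ± 0.03 CPM (limma adjusted p = 0.023), a call that ended without 3 of the 4 libraries (highest adjusted p = 0.131). The medians were -0.46 and -0.51 (exact two-sided permutation of the 24 genes, p = 0.763). Genes are not independent replicates. The maternally expressed genes that fell were H19 and Igf2r (log2 fold changes -0.95 and -0.49) and Meg3, Rian and Mirg. The last named, Meg3, Rian and Mirg, are all on chromosome 12. If they are controlled together, the similar medians rest in part on the same locus counted repeatedly. The permutation therefore cannot exclude the hypothesis. The call of Cdkn1c ended without wild-type library 2 or either knockout library, and that of Meg3 without knockout library 2. Among paternally expressed genes, the call of Dlk1 ended without either knockout library and that of Kcnq1ot1 without knockout library 1. The labels do not say how many knockout clones the libraries represent, so differences between clones and the genotype cannot be separated in any of these patterns.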
